A study of Mus musculus with 6 samples.

How the data were processed

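RNA from 6 samples of mouse lymphoma cells was hybridised to Affymetrix arrays after labelling with a 3′ in vitro transcription kit, per the labels' protocols. The deposited values are on a log2 scale, with 1 value per probe set and array, and were made by robust multi-array average (RMA), per the submitters' processing notes. RMA corrects the background, normalizes all arrays to 1 distribution and summarises the probes of a set, which pulls arrays together and tends to compress the folds of dim genes. Its version and settings, the genome build and the probe set definition are not given in the sources used here. The log2 scale was taken from the range of the values, 3.97 to 14.6, and from the array medians, which lay between 8.43 and 8.51.

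Each array held 21212 probe sets. Of these, 18786 were paired with 1 gene symbol in the platform annotation, 6 with several and 2420 are unnamed here; the last 2 kinds were not tested. For 18743 probe sets the identifier was the gene's Entrez number, so nearly every gene had 1 probe set, and for 18775 the symbol was looked up by that number in a table of mouse genes of assembly GRCm38.p6, used for names only. Where a gene had more than 1 probe set (2 genes), the one with the highest mean over the 6 arrays was used. This left 18784 genes, with no filter on dim genes. Some genes are not reported here: 1 of the 5 genes fixed by name, and 41 of the 523 members of the gene lists, were not measured among these genes, which left 482 members.

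Samples were grouped by the hairpin in the labels, 3 arrays with Rluc.713 and 3 with Dhx9.1241. The design, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The difference Dhx9.1241 minus Rluc.713 was fitted for every gene with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes; a gene was called at an adjusted p under 0.05. All adjusted p-values of genes are from this two-sided limma test. The 95% intervals of log2 changes are from the same model. Fold values are the mean difference taken out of the log2 scale.

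The 18 gene lists covered p53 target genes, the BCL-2 family, MYC-linked growth, DNA replication, mitosis, DNA damage response, interferon-stimulated genes, NF-kB targets, B cell genes, antigen presentation, stress responses, DExD/H-box helicases other than Dhx9, oxidative phosphorylation, glycolysis, cholesterol synthesis, and markers of fibroblasts, T and NK cells and myeloid cells. They were written from general knowledge, not chosen on these samples. Each was tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 18 lists, with an estimated correlation and with fry as alternatives. Members were counted at the threshold over all genes and again adjusted over the list alone.

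The genes named in the text were those fixed by name, Dhx9, Dhx29, Myc and Bcl2 among them; the 10 with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, leaving out clone, predicted and expressed-sequence names; and in each list up to 4 called members with the largest change, or the 2 members with the largest change where none was called. Further members are given as examples of their list.

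Alternatives were the mean over a gene's probe sets, 2 filters on dim genes, quantile normalization again, centring each array on its median, limma with a variance trend and robust estimation, array weights, the replicate number as a block, every probe set tested alone, and leaving out each array in turn. Cyclic loess normalization and leaving out 2 arrays together were added after the data were seen, as were comparisons of each list with 10000 random lists of matched level. Leaving out multi-transcript probe sets was planned, but 0 probe sets were of the kinds concerned, so it was not run.

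The fit was tested on simulated data for Dhx9.1241 against Rluc.713 over 18784 genes in 10 runs. It recovered 38.9% of genes changed by 0.3 on the log2 scale, 77.7% of those changed by 0.5, 98.2% of those raised by 1 and 96.8% of those changed by -1, and 4.04% of its calls were false. A list shifted by 0.3 was called by camera in 100% of runs, with 0 false lists. The simulated genes varied independently, so this does not test camera on correlated genes. Deviations of an array that are shared across genes, as seen for control replicate 1, were not simulated. The recovered and false shares may therefore differ on the real arrays.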

Results

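Gene expression was measured in cultured mouse B lymphoma cells that lack the tumour suppressor Arf and carry the Eµ-myc and Bcl-2 transgenes. Eµ-myc drives the MYC oncoprotein from an immunoglobulin enhancer in B cells. The cells were grown on layers of irradiated Arf-null mouse embryonic fibroblasts and had been transduced with 1 of 2 short hairpin RNAs. There were 3 arrays from cells with the control hairpin Rluc.713, named for the Renilla luciferase gene, and 3 from cells with Dhx9.1241, which is named for Dhx9, a DExH-box helicase that unwinds RNA and DNA. The study asked which factors modify the response of MYC-driven lymphomas to ABT-737, an inhibitor of BCL-2, BCL-XL and BCL-W. The labels name no drug treatment on these 6 arrays, so the comparison is of the hairpins alone. Nothing in the labels says whether the 3 arrays of a hairpin came from separate cultures, and the p-values measure the spread between these arrays, which may be technical. The number of arrays, 3 in each group, limits the precision.

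The gene named by the hairpin was lower in the Dhx9.1241 cells. The Dhx9 level (probe set 13211_at) was 12.42 ± 0.063 on the log2 scale in the control (SD, n = 3) and 11.42 ± 0.041 in Dhx9.1241 (SD, n = 3), and it lay below all controls on all 3 Dhx9.1241 arrays. The log2 change was -0.99 (SE 0.053, 95% interval -1.12 to -0.87, adjusted p = 0.000129), a level 1.99-fold lower. Sample titles call the same arrays knockdowns of Dhx29, which encodes another DExH-box helicase that acts in translation initiation. Dhx29 (218629_at) was at 10.41 ± 0.059 in the control and 10.45 ± 0.047 in Dhx9.1241, a log2 change of 0.04 (SE 0.053, interval -0.08 to 0.17, adjusted p = 0.857). The arrays are therefore referred to by the hairpin, Dhx9.1241. The probe sets of the mouse genes Myc and Bcl2 did not pass the threshold, and whether they read the transgene transcripts was not tested: Myc had a log2 change of 0.14 (SE 0.052, adjusted p = 0.239) and Bcl2 of -0.09 (SE 0.049, adjusted p = 0.532). Myc passed under 1 alternative, limma with a variance trend and robust estimation (adjusted p = 0.0174, against 0.0913 to 0.546 under the others). The plot of named genes by array gives these levels.

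**Figure D1:**
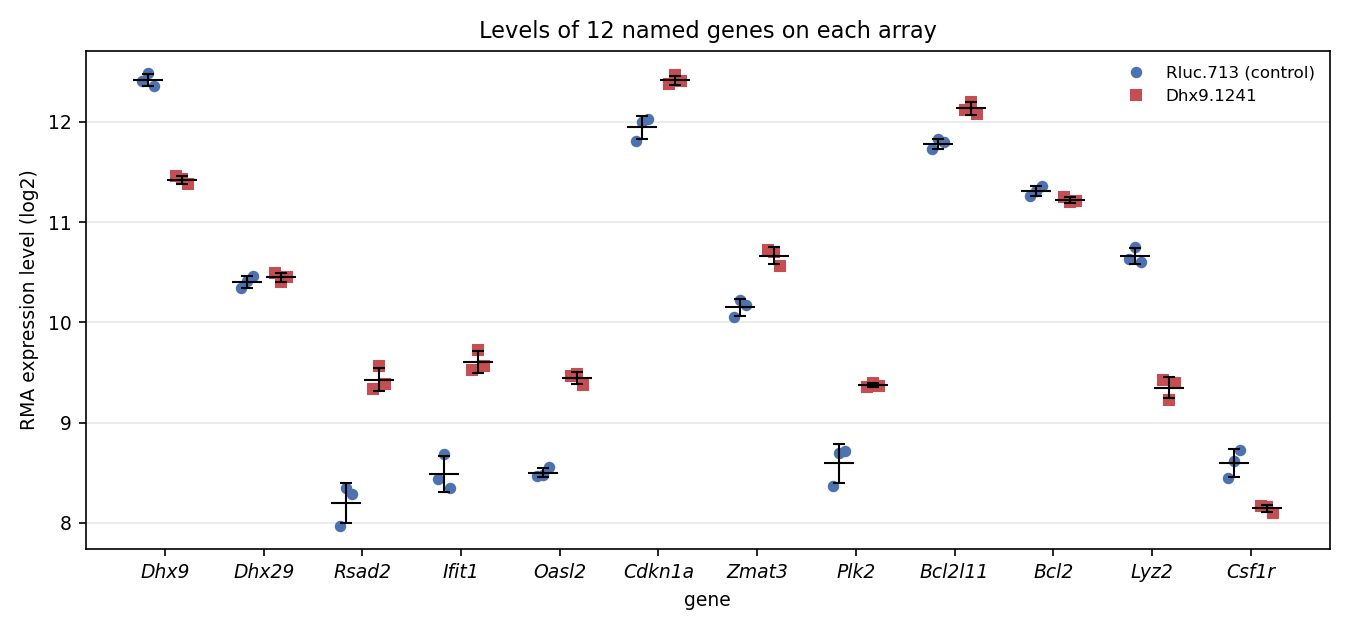
RMA expression level (log2, vertical axis) of 12 named genes (horizontal axis) on each of the 3 Rluc.713 arrays (circles) and 3 Dhx9.1241 arrays (squares), with lines for the mean and bars for the SD. Dhx9 fell from 12.42 to 11.42, while Dhx29 stood at 10.41 and 10.45.

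Of 18784 genes, 389 were higher and 201 lower in Dhx9.1241 at an adjusted p under 0.05, 3.14% of the genes tested, and most of these changes were small. The median log2 change was 0.36 among the genes that rose and -0.36 among those that fell, and 8 genes rose and 4 fell at least 2-fold. The largest rise among genes with a full name was that of Apobec2, a member of the cytidine deaminase family, from 8.37 ± 0.128 to 10.05 ± 0.091 (SD, n = 3), a 3.21-fold increase. Fam221a rose 2.92-fold, the Ras exchange factor gene Rasgef1a 2.62-fold, Rassf6 2.37-fold, and the antiviral genes Rsad2 and Ifit1 rose 2.35-fold and 2.17-fold. The vitamin C transporter gene Slc23a1 rose 2.01-fold, and Lipg, Myzap and Tmem163 rose by log2 changes of 0.98, 0.98 and 0.95. The rule for named genes left out clone names, and 1 such gene, 1700001P01Rik, chosen after its values were seen, had a larger log2 change of 2.07 (SE 0.168, adjusted p = 0.000891), and E330020D12Rik had one of 0.97, above that of Tmem163.

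The largest fall was that of Lyz2, the lysozyme of macrophages and neutrophils, from 10.66 ± 0.076 to 9.35 ± 0.103 (SD, n = 3), a level 2.49-fold lower. The nucleotide hydrolase gene Dnph1 was 2.17-fold lower, Pla2g7, which encodes an enzyme that degrades platelet-activating factor, 2.15-fold lower, and the chemokine receptor gene Ccr1 2.09-fold lower. Among genes with a full name, next to Dhx9 itself came the histone gene H3c15 (log2 change -0.97), the growth factor gene Tgfb3 (-0.92), the IgM receptor gene Fcmr (-0.90), the cysteine synthesis gene Cth (-0.81) and the mitochondrial import gene Timm8a1 (-0.77). The clone-named I830077J02Rik, chosen after its values were seen, fell by 0.87 (adjusted p = 0.000891). H3c15 has near-identical histone paralogs and its value is uncertain; its call was lost without Dhx9.1241 replicate 1 (adjusted p = 0.0525). The call of Timm8a1 was lost without control replicate 2 (0.061) and without Dhx9.1241 replicate 3 (0.0598). Every one of the 590 changed genes had groups that did not overlap, as did 3768 of all genes (20.1%, against 10% by chance for 3 against 3).

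The number of changed genes moved when any 1 array was left out. Such a fit has fewer arrays, which by itself lowers its power. A call lost in it, here or below, does not by itself show that the result rested on that array. All 590 called genes kept their sign in each of these fits. Without control replicate 1, 497 genes were higher and 399 lower, more than the 389 and 201 with all arrays although the fit had fewer arrays. The counts were 172 and 77 without control replicate 2, 203 and 86 without control replicate 3, 126 and 79 without Dhx9.1241 replicate 1, 165 and 83 without Dhx9.1241 replicate 2, and 153 and 70 without Dhx9.1241 replicate 3. Control replicate 1 stood apart from the other controls on the second principal component, at 16.7 against -4.81 and -5.29, as the plot of the arrays shows. Genes that rose made up 65.9% of the calls with all arrays and 55.5% without control replicate 1.

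**Figure D2:**
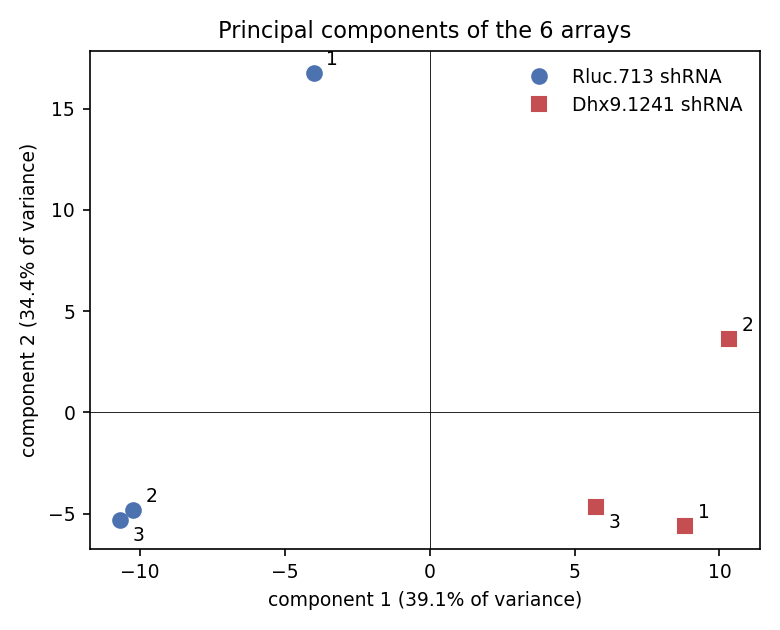
Positions of the 6 arrays, numbered by replicate, on the first 2 principal components of the gene levels, with circles for Rluc.713 and squares for Dhx9.1241; the axis labels give each component's share of the variance. Component 1 (39.1%) separates the hairpins, and control replicate 1 stands apart on component 2 (34.4%).

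Many interferon-stimulated genes rose in Dhx9.1241. Of 30 measured members of this list, 11 rose, 1 fell and 18 did not pass the threshold. The antiviral effector genes Rsad2 and Ifit1 led the list, with log2 changes of 1.23 (SE 0.104, adjusted p = 0.000972) and 1.12 (SE 0.094, adjusted p = 0.000961). Oasl2, of the oligoadenylate synthetase-like family, rose from 8.50 ± 0.047 to 9.44 ± 0.061 (SD, n = 3), and the chemokine gene Cxcl10 from 8.71 ± 0.051 to 9.53 ± 0.077. Ifit3 (0.80), Oasl1 (0.67), the cytosolic RNA sensor gene Ifih1 (0.59), Rtp4 (0.55), Usp18 (0.49), the transcription factor gene Irf7 (0.39) and Ifi27 (0.36) made up the rest, while Parp14 fell by 0.26 (adjusted p = 0.0484). Among the members that did not pass, Oas1a (0.05), Oas3 (0.04), Eif2ak2 (-0.07) and Trim30a (0.02) changed little. Others of them were higher in the mean, such as Ifit2 (0.28), Irf9 (0.26) and Bst2 (0.20). The Parp14 call was lost in 5 of the 6 fits without 1 array, all but that without control replicate 1, with the replicate number as a block and with each array centred on its median. Adjusted over the list alone, 15 rose and 1 fell. The list median was a log2 change of 0.19, and camera, limma's test of a list against all other genes, gave an adjusted p of 1.86e-11 with its preset inter-gene correlation; the adjusted p was 0.21 with an estimated correlation. Without control replicate 1, 11 members rose, the same number as with all arrays. Leaving out any other array gave 8 to 10, the fewest without Dhx9.1241 replicate 3, and the replicate number as a block gave 9. The count was 12 after quantile normalization again, after cyclic loess and with a variance trend and robust estimation, and 13 with array weights. Among genes at or above the median level, 16 members were left, of which 7 rose and 1 fell.

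Camera with the preset correlation called 7 of the 18 lists, and none with an estimated correlation, where its smallest adjusted p was that of the interferon list. Fry, which tests whether a list's genes move one way on balance, called 3 of them: the interferon, p53 and myeloid lists. When the 6 arrays were split into 3 and 3 in the 9 other ways, the preset correlation called 3 to 8 lists. These splits do not give a rate of false calls. Each puts unequal numbers of Dhx9.1241 arrays on its sides, so part of the hairpin difference stays in the comparison. The plot of the lists gives every member.

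**Figure D3:**
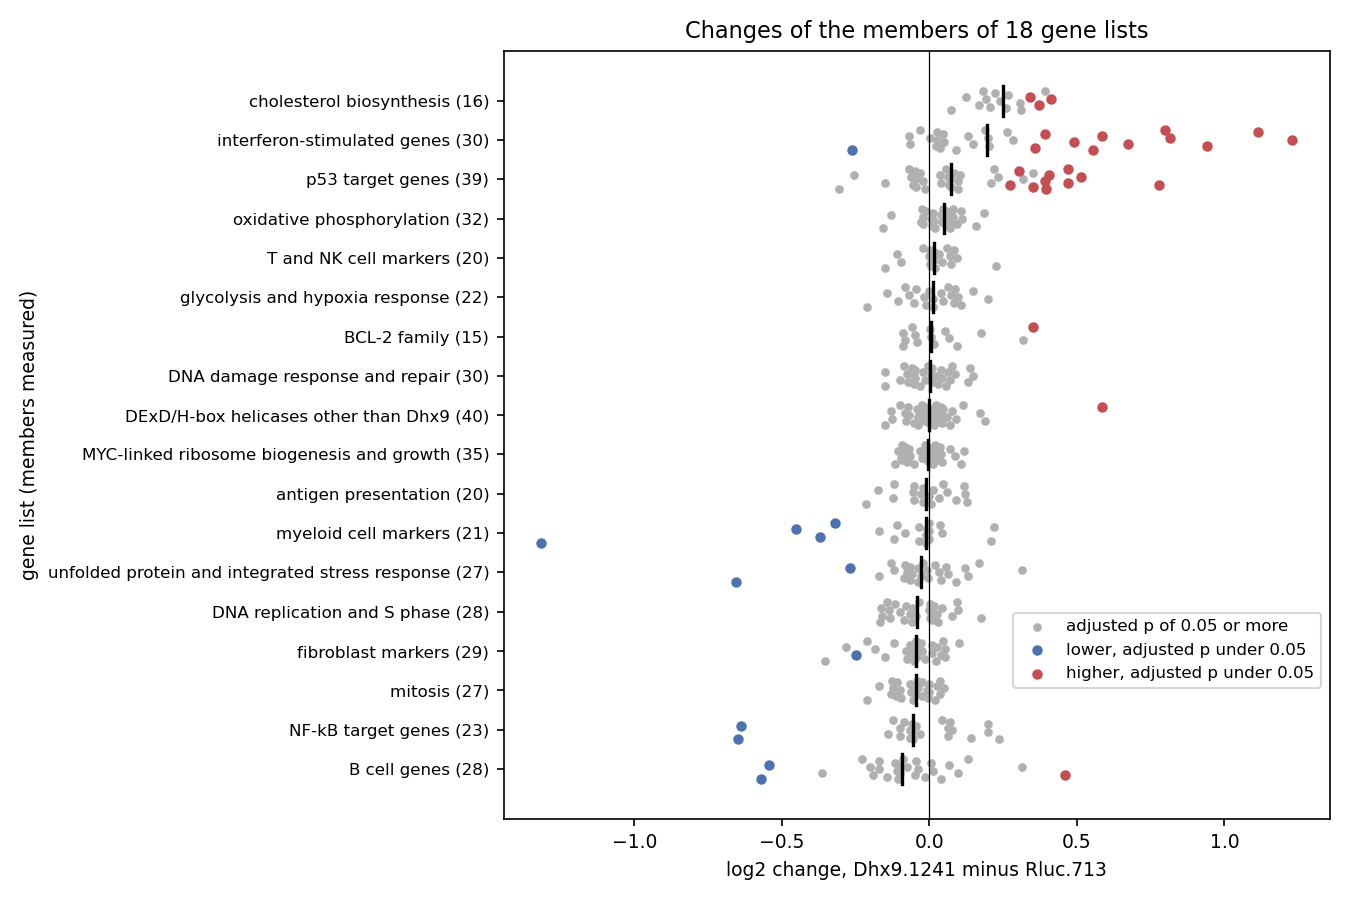
Log2 change (Dhx9.1241 minus Rluc.713, horizontal axis) of each measured member of the 18 gene lists (vertical axis, number measured in parentheses), 1 point per gene, with a vertical bar at each list's median. Red points are higher and blue points lower at an adjusted p under 0.05; 11 of 30 interferon-stimulated genes and 10 of 39 p53 target genes are red.

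Of 39 measured p53 target genes, 10 rose, none fell and 29 did not pass the threshold. The polo-like kinase gene Plk2 rose most, from 8.59 ± 0.196 to 9.37 ± 0.02 (SD, n = 3), followed by the RNA-binding protein gene Zmat3 (log2 change 0.51, SE 0.065), Trp53inp1 (0.47, SE 0.047) and Cdkn1a (0.47, SE 0.067), which encodes the cell cycle inhibitor p21. The others were Phlda3 (0.41), Slc19a2 (0.39), Sesn1 (0.39), Psrc1 (0.35), the death receptor gene Tnfrsf10b (0.30) and Ak1 (0.27). Other members of the list did not pass, among them Mdm2 (0.10, interval -0.02 to 0.22), Bbc3 (0.07), Ccng1 (-0.05) and Aen (-0.05). Adjusted over the list alone, 14 rose and 1 fell, and 2 were lower at an unadjusted p under 0.05. Camera gave an adjusted p of 2.36e-06, and 0.421 with an estimated correlation. Fewer members rose without control replicate 2 (6) or replicate 3 (7), without Dhx9.1241 replicate 1 (5), replicate 2 (6) or replicate 3 (6), without both control replicate 1 and Dhx9.1241 replicate 2 (9), and with the replicate number as a block (7). More rose, and 1 fell, with array weights (14), with a variance trend and robust estimation (13), among genes at or above the median level (13), after cyclic loess (12), after quantile normalization again (11) and without control replicate 1 (11). Cdkn1a lost its call without Dhx9.1241 replicate 3 (adjusted p = 0.0545).

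In the BCL-2 family, the proteins that ABT-737 acts on and their partners, 1 of 15 measured members rose and 14 did not pass. The member that rose was Bcl2l11, which encodes the BH3-only protein BIM, from 11.78 ± 0.051 to 12.13 ± 0.061 (SD, n = 3), a 1.28-fold increase with an adjusted p of 0.0132. Pmaip1, which encodes the BH3-only protein NOXA, had a log2 change of 0.32 (adjusted p = 0.0902), and Bmf 0.18, Mcl1 -0.08 and Bcl2l1, the gene of BCL-XL, -0.09. Adjusted over the list alone, 2 members rose, as with array weights, with a variance trend and robust estimation and among genes at or above the median level. The list did not pass (adjusted p = 0.652), and the Bcl2l11 call was lost without Dhx9.1241 replicate 1 (0.0651) or replicate 2 (0.0632).

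Genes of cholesterol synthesis lay higher in Dhx9.1241. All 16 measured members had a positive change, with a median of 0.25, and 3 passed the threshold over all genes: Fdft1, which encodes squalene synthase, from 11.94 ± 0.041 to 12.36 ± 0.068 (SD, n = 3), Tm7sf2 (0.37, SE 0.071) and Sc5d (0.34, SE 0.071), both of later sterol steps. Mvd (0.39), Msmo1 (0.31), Lss (0.31) and the transcription factor gene Srebf2 (0.12) did not pass. Adjusted over the list alone, 14 of the 16 rose. Camera gave an adjusted p of 6.08e-11, and 0.421 with an estimated correlation. A smaller camera p came from 1 other split of the arrays, which also holds part of the hairpin difference. Without control replicate 2 or 3, or Dhx9.1241 replicate 1 or 2, 1 member passed, and without Dhx9.1241 replicate 3, 2 passed. More passed with a variance trend and robust estimation (8), among genes at or above the median level (6) and with array weights (5). Fdft1 passed without any 1 array, while Tm7sf2 passed in 2 and Sc5d in 1 of these 6 fits.

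The B cell list held falls and a rise. Of 28 measured members, Vpreb3, a gene of the pre-B cell receptor family, fell from 13.04 ± 0.012 to 12.47 ± 0.039 (SD, n = 3), Spib, a transcription factor gene of the B lineage, fell from 12.20 ± 0.097 to 11.65 ± 0.115, and the recombinase gene Rag1 rose from 9.49 ± 0.056 to 9.95 ± 0.14. The other 25 did not pass, among them Cd79a (-0.11), Pax5 (-0.05) and Ms4a1 (0.31). Adjusted over the list alone, 2 rose and 4 fell. The counts were 2 higher and 6 lower with a variance trend and robust estimation, 2 and 4 with array weights, and 1 and 4 without control replicate 1. The list median was -0.09 and camera gave an adjusted p of 0.000305, and 0.582 with an estimated correlation. The Rag1 call was lost without control replicate 2 (adjusted p = 0.0615), Dhx9.1241 replicate 1 (0.0687) or replicate 3 (0.0871).

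Among markers of other cell types, 4 of 21 measured myeloid genes fell and none rose. Lyz2 fell most, by 1.31 on the log2 scale, followed by Csf1r, the receptor of macrophage colony-stimulating factor (-0.45, SE 0.073), and the signalling adaptor genes Tyrobp (-0.37, SE 0.047) and Fcer1g (-0.32, SE 0.058). The other 17 did not pass, and Fcgr3 (0.22) and Itgam (0.21), which were higher in the mean, were past the threshold when adjusted over the list alone, with 2 higher and 4 lower. Over all genes, 1 myeloid marker was higher after quantile normalization again, after cyclic loess, with a variance trend and robust estimation and among genes at or above the median level. The median of the list was -0.01, and camera gave an adjusted p of 0.00644, and 0.254 with an estimated correlation. Without control replicate 2, or any 1 of the Dhx9.1241 arrays, 2 members fell; Csf1r passed in 2 and Fcer1g in 1 of the 6 fits without 1 array. Of 29 fibroblast markers, the cell type of the feeder layer, Cav1 fell (-0.25, SE 0.053) and 28 did not pass, and the count was the same over the list alone; 2 were lower with array weights. The fibroblast list was called by camera (adjusted p = 0.0083), but not without control replicate 1 (0.668) nor with an estimated correlation (adjusted p = 0.74). Cav1 passed in 0 of the 6 fits without 1 array, and with all arrays 5 members were lower at an unadjusted p under 0.05. None of 20 T and NK cell markers passed in the main limma test, over all genes or the list alone, and 1 was higher at an unadjusted p under 0.05; Klrb1c (0.22) and Zap70 (-0.15) had the largest changes, and the list's adjusted p was 0.727.

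In the main limma test no measured member of the mitosis, DNA replication, MYC-linked growth or DNA damage lists passed the threshold. None of 27 mitosis genes passed, over all genes or the list alone, and 3 were lower at an unadjusted p under 0.05; Top2a, the DNA topoisomerase of dividing cells (-0.21, SE 0.056), and Nusap1 (-0.17, SE 0.068) had the largest changes. The mitosis list had a median of -0.05 and was called by camera (adjusted p = 0.00593), but not without control replicate 3 (0.0693) or Dhx9.1241 replicate 2 (0.0987), and its adjusted p was 0.805 with an estimated correlation. None of 28 DNA replication genes passed (list adjusted p = 0.0649), with 1 higher and 5 lower at an unadjusted p under 0.05, and Ccne1 at 0.17 and the helicase gene Mcm4 at -0.17. The same held for 35 MYC-linked ribosome biogenesis and growth genes (list adjusted p = 0.317, 1 higher and 1 lower unadjusted), where Bop1 stood at 0.12 and Pes1 at -0.12, and for 30 DNA damage response genes (0.727, 2 higher and 2 lower unadjusted), where H2ax and Nbn both stood at -0.15. Adjusted over each list alone, none of these passed either. Without control replicate 1, camera called the replication (0.00242), growth (0.0139) and damage (0.0183) lists, all in the lower direction. After cyclic loess none of these lists was called (0.0985, 0.773 and 0.773). The lists were bright, with median levels of 11.5, 12.3 and 10.8 against 8.47 over all genes. Control replicate 1 differed from the other controls by signal level, as described below, and whether that shift made these calls was not tested. The replication list was also called without Dhx9.1241 replicate 3 (0.0327), with array weights (0.00724) and without both control replicate 1 and Dhx9.1241 replicate 2 (0.0102), and the growth list with array weights (0.04) and without both arrays (0.0344). Single members passed under some alternatives: 2 mitosis genes were lower, and 1 replication gene higher and 2 lower, with a variance trend and robust estimation. With array weights 1 was lower in each of the mitosis and replication lists, and among genes at or above the median level 1 mitosis gene was lower and 1 replication gene higher and 1 lower. With all arrays the damage list had a median of 0.0011 and a mean of -0.00084.

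Of 23 NF-kB target genes, the cytokine genes Tnf and Ccl3 fell and 21 did not pass. Tnf fell from 10.70 ± 0.061 to 10.05 ± 0.054 (SD, n = 3), and Ccl3 from 11.02 ± 0.172 to 10.38 ± 0.257. Inhibitor and feedback genes of the pathway, Nfkbia (-0.03) and Tnfaip3 (0.20), did not pass. Adjusted over the list alone, 1 rose and 2 fell, and camera did not call the list (adjusted p = 0.204). Ccl3 kept its call in 1 of the 6 fits without 1 array, that without Dhx9.1241 replicate 2, and its adjusted p reached 0.178 without Dhx9.1241 replicate 1. None of 20 antigen presentation genes passed in the main limma test, over all genes or the list alone, with 2 lower at an unadjusted p under 0.05, Psmb8 at -0.21 and Tapbp at -0.17 (list adjusted p = 0.498); Tapbp passed without control replicate 1 (0.0468), and 1 member was lower with a variance trend and robust estimation, with array weights and among genes at or above the median level. The last 2 settings, and leaving out control replicate 1, called 1 NF-kB target gene higher.

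In the unfolded protein and integrated stress response list, Chac1, which encodes a glutathione-degrading enzyme, fell from 10.55 ± 0.122 to 9.90 ± 0.129 (SD, n = 3), and the serine synthesis gene Psat1 fell from 13.14 ± 0.051 to 12.88 ± 0.0043. The other 25 of 27 members did not pass, including Atf4 (-0.12), Ddit3 (-0.08), Hspa5 (0.06) and Atf3 (0.31, adjusted p = 0.0532). Over the list alone, 1 rose and 2 fell, and with a variance trend and robust estimation 2 rose and 3 fell. The list was not called (adjusted p = 0.196); it was called without control replicate 1 (0.0482) and without both that array and Dhx9.1241 replicate 2 (0.0159). Psat1 passed in 1 of the 6 fits without 1 array, that without control replicate 1. Of 40 DExD/H-box helicases other than Dhx9, Ifih1, which is also in the interferon list, rose and 39 did not pass. The count was the same over the list alone, and 1 helicase gene was lower with a variance trend and robust estimation. The helicase list was not called (0.899), with a mean of 0.013 and a median of -0.00079, except without control replicate 1 (0.0447, lower). The stress and helicase lists were also bright (median levels 11.6 and 11.2). Neither was called after cyclic loess (0.429 and 0.886).

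Energy metabolism genes had no member past the threshold in the main limma test, over all genes or over the lists alone. With a variance trend and robust estimation, 2 oxidative phosphorylation genes were higher, and 1 glycolysis and hypoxia gene was higher and 1 lower. Quantile normalization again, cyclic loess, array weights and the filter at the median level each called 1 oxidative phosphorylation gene higher. Of 32 oxidative phosphorylation genes, 25 had a positive change, 2 were higher and 1 lower at an unadjusted p under 0.05, and the median was 0.05. Ndufv1 of complex I (0.19, adjusted p = 0.0892) and Sdha of complex II (0.16) had the largest positive changes, and the list's adjusted p was 0.0549. It was called with a variance trend and robust estimation (0.00549), after quantile normalization again (0.00893) and after cyclic loess (0.0099), and without control replicate 2 (0.0294), control replicate 3 (0.0424) or Dhx9.1241 replicate 1 (0.0483). Of 22 glycolysis and hypoxia genes, 2 were higher and 2 lower at an unadjusted p under 0.05, with Vegfa at -0.21 and P4ha1 at 0.20, and the list's adjusted p was 0.899.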

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

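Cyclic loess and leaving out control replicate 1 together with Dhx9.1241 replicate 2 were chosen after the data were seen; the other alternatives were planned. The change of Dhx9 stayed past the threshold in all of them, between -1.02 and -0.96, and that of Dhx29 stayed within 0.01 to 0.07 and did not pass. All 590 called genes kept their sign wherever they were tested. Genes at least 2-fold higher numbered 7 to 9 and at least 2-fold lower 3 to 6. Counts of changed genes moved more, and for the filter fewer genes were tested, while the other causes were not tested. Genes higher and lower, 389 and 201 with all choices as described, were 609 and 382 among genes at or above the median level, 517 and 353 after quantile normalization again, 673 and 466 with a trend and robust estimation, 669 and 542 with array weights, 508 and 341 after cyclic loess, 278 and 185 with each array centred on its median, and 349 and 256 without both arrays. Leaving out 1 array gave 126 to 497 higher and 70 to 399 lower. With the replicate number as a block the counts were 172 and 92, and 5 named genes lost their call (Timm8a1, Psat1, Sc5d, Cav1 and Fcer1g). The labels do not say that the numbers pair arrays. Deviations of same-numbered arrays correlated by -0.27, -0.34 and 0.24, and control replicate 1 went best with Dhx9.1241 replicate 2 (0.48). With 3 arrays in a group, these values cannot show whether same-numbered arrays share a batch or culture. Of 59 named genes other than the 2 helicases, 0 reversed under any alternative, and leaving out 1 array ended 2 to 10 of the 41 calls. The number of lists called, 7, was 0 with an estimated correlation, 3 with fry and 6 to 11 when 1 array was left out. With an estimated correlation, adjusted p-values were 0.421 (p53 targets), 0.21 (interferon), 0.421 (cholesterol), 0.582 (B cell), 0.805 (mitosis), 0.74 (fibroblast) and 0.254 (myeloid). With fry they were 0.119 (B cell), 0.0943 (cholesterol), 0.408 (mitosis) and 0.504 (fibroblast). The fibroblast list also lost its call among genes at or above the median level (0.103), with array weights (0.257) and without both arrays (0.307), and the myeloid list among genes at or above the median level (0.114), where 6 members were left. Leaving out 1 array gave 0.000174 to 0.0987 for mitosis and 0.000417 to 0.668 for fibroblasts. Leaving out multi-transcript probe sets was not run, since it removed 0 probe sets. Signal over background was not used here to set which dim genes were measured.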

Other observations

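The genes in this and the next paragraph were picked after their values were seen. Histone genes outside any list moved in part. Of 47 measured histone genes taken by their symbols, 5 fell, 1 rose and 41 did not pass, with a median log2 change of -0.03. Those that fell were H3c15 (-0.97), H3c14 (-0.73), the linker histone gene H1f2 (-0.58), H2bc21 (-0.54) and H2ac6 (-0.41), and H2ac1 rose by 0.76. Near-identical paralogs can share probes, and which copy changed is uncertain.

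Single genes outside the lists that fell, picked by hand from the changed genes and not tested as a group, were the complement receptor gene C3ar1 (-0.64, SE 0.095), the properdin gene Cfp (-0.63, SE 0.076), the inflammasome gene Nlrp3 (-0.74, SE 0.092) and the chemokine gene Ccl6 (-0.74, SE 0.107), with Cd63 at -0.68 and Mgst1 at -0.67. Single genes that rose, picked in the same way, were the costimulatory ligand gene Cd80 (from 9.51 ± 0.168 to 10.44 ± 0.058; SD, n = 3), Rasgrp1 (0.89), Itgb7 (0.86), Zbtb32 (0.85), Klf3 (0.84), the aryl hydrocarbon receptor gene Ahr (0.79) and Prkcb (0.67). The chemokine receptor gene Ccr6 fell by 0.61, and Adam19 and Ltbp4 by 0.75 and 0.73. All of these passed the limma threshold.

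All tests from here on were chosen after the results they bear on were seen. Control replicate 1 stood apart from control replicates 2 and 3. Its Dhx9 level was 12.405, near the mean of 12.42 of the other controls and far from the 11.42 of Dhx9.1241, with a pooled SD of 0.053, which argues against a knockdown array under a control label. Its difference from the other controls followed the signal level across genes (Spearman's rho -0.46, against 0.043 for control replicate 2 minus replicate 3; genes are not independent replicates), with medians of -0.10 to 0.15 over deciles of level, so a shift by signal level may account for part of it. Dhx9.1241 replicate 2 deviated partly along with it (correlation of deviations 0.48), but followed the signal level less (rho -0.21). Its mean correlation with its own group was 0.9984, against 0.9985 and 0.9986 for the other Dhx9.1241 arrays and 0.9969 for control replicate 1. No biological explanation was tested.

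The rise of interferon-stimulated genes does not rest on control replicate 1, since 11 members were higher without it. Myeloid cells added to the Dhx9.1241 cultures would be expected to raise the abundant myeloid markers. The 4 most abundant had a median log2 change of -0.34, with 3 of them lower. Fcgr3, the most abundant, stood at 0.22 and did not pass. Whether the lymphoma cells transcribe these markers was not tested. A fall within those cells could hide added myeloid cells, so the values do not decide. With 1 Dhx9 hairpin on the arrays, a response to the hairpin or an off-target of it cannot be told apart from a response to less Dhx9, and either may raise these genes. Ifnb1, the interferon beta gene, picked after its values were seen, was at 6.71 in the control and 6.67 in Dhx9.1241 (log2 change -0.04, SE 0.057, adjusted p = 0.908). These levels lay below the lower quartile of every array, 7.17 to 7.29. A change in so dim a gene could go unseen, so its value does not decide whether interferon was induced.

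The fall of 4 of the 21 myeloid markers, in a list whose median was -0.01, does not rest on control replicate 1 alone, since 4 members were lower without it. Fewer admixed myeloid cells in the Dhx9.1241 cultures would lower all abundant markers: of the 6 members above the median level of all genes, 3 fell, 0 rose and 3 did not pass, with a median of -0.14. Lyz2, Tyrobp and Fcer1g fell, while Fcgr3, Itgam and Mrc1 stood at 0.22, 0.21 and 0.04. How many of the 21 markers the lymphoma cells transcribe themselves was not tested, so a different share of cells and a change within the lymphoma cells cannot be told apart from these values, and either may contribute.

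The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each of the other splits also puts arrays of both hairpins on each side. The hairpin difference then adds to the spread within a side, which can lower the number of called genes, so those counts do not measure chance. The sides also hold unequal numbers of Dhx9.1241 arrays, so part of the hairpin difference can still give list calls. The counts and p-values of lists in those splits do not measure chance either. The real split gave 590 changed genes and the highest of the others 0 (1 of 10 splits as large, the real one), although up to 2460 genes in another split had an unadjusted p under 0.05 in limma. For genes changed at least 2-fold the counts were 12 and 0 (1 of 10). For gene lists called by camera the real split gave 7 and the highest other 8, and 4 of 10 splits gave at least as many; the 3 other splits among them each put control replicate 1 with 2 Dhx9.1241 arrays. The real split gave the smallest camera p of the 10 for the interferon, p53 and myeloid lists; of the others called, 2 of 10 splits gave a p as small for the cholesterol and B cell lists, 3 for mitosis and 4 for fibroblasts. The list medians were also compared with 10000 random lists of matched level, a comparison added after the data were seen. They lay at percentile 100 for the interferon and cholesterol lists, 99.96 for p53 targets and 99.92 for oxidative phosphorylation. Percentiles were 0 for B cell genes, 0.04 for fibroblast markers, 0.13 for NF-kB targets, 2.31 for mitosis, 2.94 for DNA replication and 18.4 for myeloid markers. Members of the random lists were drawn independently. The percentiles therefore ignore correlation within a list and can overstate how far it stands apart.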
